A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

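The data are gene expression profiles of budding yeast (Saccharomyces cerevisiae) on 15 one-colour Affymetrix Yeast Genome 2.0 arrays. Per the labels, 5 strains of the W303 background were grown to mid-log phase in rich medium with added adenine, total RNA was purified on columns, and biotin-labelled cRNA was made in a single amplification cycle. The labels give 3 biological replicates per strain and no growth temperature. The strains are WT1B (mating type alpha) with its mutants rpb1-1 and rpb1S751F, and WT1A (mating type a) with its mutant rpb2-10. The rpb1 alleles affect the largest subunit of RNA polymerase II, encoded by RPO21, and rpb2-10 affects the second largest subunit, encoded by RPB2.

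The deposited values are log2 expression levels, one per probe set and array, and RMA and limma are named in the submitters' processing notes without versions. RMA corrects the background, quantile-normalizes the arrays it is given and summarises the probes of each probe set. Quantile normalization gives the arrays like distributions, so a change common to most genes would not be seen. Higher and lower therefore mean relative to the other genes, and near-even counts of both do not speak against a common change. The role of limma, the probe annotation and any filter are not given in the sources used here. Median levels of the tested genes lay between 10.04 and 10.09 on the 9 arrays of alpha strains and between 7.75 and 7.83 on the 6 arrays of a strains. The arrays therefore appear as 2 sets normalized apart, and this split coincides with the mating type. Each mutant shares its set with its own wild type. Only the contrast between the wild types compares levels directly across the sets. Levels of mating-type genes across them are given after subtraction of each array's median over the tested genes. Comparisons of effects between mutants of alpha and a strains also cross the sets, as do overlaps and correlations of these effects. Each effect is taken within its own set, which removes a constant offset, but other differences between the sets may remain.

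The table holds 10928 probe sets. Names came from the platform annotation given with the data, with 12 symbols updated through a reference gene table of assembly R64. Of the probe sets, 5498 named 1 S. cerevisiae gene, 1 named several, 1746 named a gene of another species and 3683 had no gene name here, of which 213 have control or reporter identifiers. The brightest probe set over all arrays was used for the 47 genes with more than 1, which left 5449 genes to test. For 115 genes the identifier of the probe set marks probes shared with other sequences, and these are called genes with shared probes. Probe sets of the other species were left out of the tests and served as a measure of background. On each array, 97.7% to 98.9% of the tested genes lay above the 95th percentile of those probe sets. No genome build is named by the files, so no coordinates are given, and the reference was used for names, neighbouring genes and lengths. All 5449 genes had a length, and 97.0% of lengths were multiples of 3, so they are called coding lengths.

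Arrays of a group were compared before use. Pearson correlations across genes between replicates ran from 0.987 to 0.998, and at most 53 of the 5449 values were identical in a pair of replicates, so each array was counted as 1 replicate. The number of arrays limits the precision. One linear model with a mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 10 residual and 2.98 prior degrees of freedom). Contrasts compared each mutant with its own wild type, the rpb1 alleles with each other, the effects of each rpb1 allele with the effect of rpb2-10, and the wild types. A gene was called at a two-sided Benjamini-Hochberg adjusted p below 0.05 over the 5449 genes. Adjusted p-values of genes come from this limma fit, and errors of log2 fold changes are its standard errors (SE) with n = 3 arrays per group.

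Before the data were examined, 31 gene lists were fixed from textbook knowledge of yeast pathways, complexes, cell cycle phases, stress responses and mating types, and all had at least 5 measured members. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with a correlation estimated per list and the fry test stand beside it. Camera asks whether a list shifts more than the other genes, and fry only whether its genes shift at all. Most genes were called in each mutant, so a list that passes fry alone shows no shift particular to that list. The rule for named genes was also fixed then. It takes RPO21 and RPB2; the 10 highest and 10 lowest called genes whose 3 mutant arrays all lie on 1 side of the wild-type arrays; up to 3 members with the smallest p from each list, or the 1 with the smallest p where none was called; the 10 genes with the largest mean absolute change among those changed the same way in all 3 mutants; the 5 highest and 5 lowest in each contrast between mutants; and the mating-type genes with the 5 highest and 5 lowest others between the wild types. Genes named outside this rule are marked as chosen after their values were seen.

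The procedure was tested on simulated data with 67, 67 and 66 of 5449 genes changed by 0.5, 1 and 2 on the log2 scale. For the comparison of rpb1-1 with WT1B, 68.7% of genes changed by 0.5 on the log2 scale, 94.0% of those changed by 1 and 100% of those changed by 2 were recovered, and 3.98% of calls were false. For rpb1S751F these values were 68.7%, 95.5%, 100% and 5.29%. For rpb2-10 they were 71.6%, 100%, 100% and 5.14%. The genes of a further list, shifted together by 0.5, counted among the calls but not as false. Noise was drawn independently per gene with 1 SD for all groups, and far fewer genes were changed than were called in the data. The shares therefore describe the procedure under these settings and do not carry over to the data. Alternatives were a filter on the dimmest 25% of genes, median centring, a further quantile normalization, fits of fewer arrays, trend and robust options, array weights, means of probe sets, stricter thresholds, a replicate block and leaving out each array. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots. The 3683 unnamed probe sets and the 1 naming several genes were left out because their genes are not named here.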

Results

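The 15 arrays cover 5 groups of 3 biological replicates, namely WT1B, rpb1-1 and rpb1S751F of mating type alpha and WT1A and rpb2-10 of mating type a. The median replicate SD of a gene was 0.11 in WT1B, 0.12 in rpb1-1 and 0.13 in rpb1S751F, and 0.07 in WT1A and in rpb2-10. The fit shares 1 variance per gene over all 15 arrays, so its SE is not the spread of the groups compared. It tends to be too small for the rpb1 alleles and too large for rpb2-10, and counts of genes are not comparable between them. All 15 arrays correlated best with an array of their own group. Fold changes are log2 values ± SE with n = 3 arrays per group, unless given on the linear scale. Each mutation was present in 1 strain. Effects of a mutant below may therefore include other differences between that strain and its wild type.

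**Figure D1:**
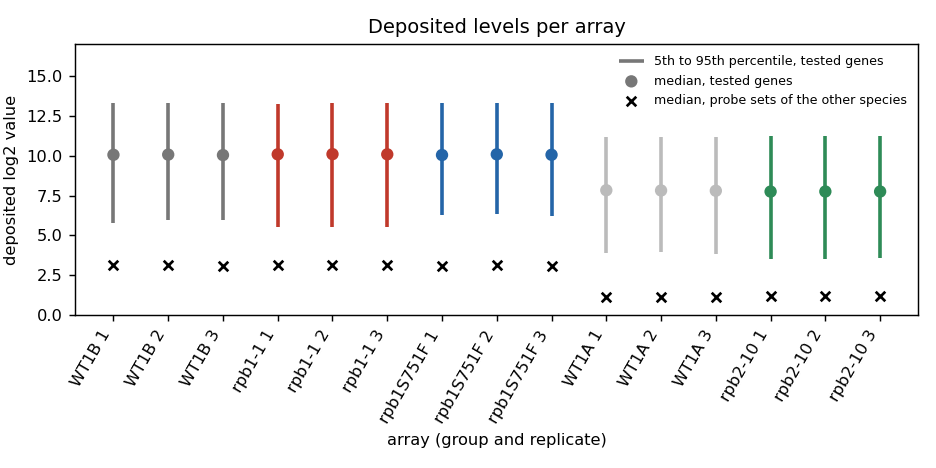
Deposited log2 values on each of the 15 arrays. Dots are the medians of the tested genes, bars span their 5th to 95th percentiles and crosses are the medians of the probe sets of another species; the 9 arrays of alpha strains lie at medians of 10.04 to 10.09 and the 6 arrays of a strains at 7.75 to 7.83.

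The wild types were compared first, because mating-type genes check the labels. After median centring, MFA2, which encodes a-factor, was 7.15 ± 0.11 higher in WT1A than in WT1B, and STE2, the receptor for alpha-factor, was 6.03 ± 0.10 higher. MF(ALPHA)1 and MF(ALPHA)2, which encode alpha-factor, were at −9.59 ± 0.19 and −7.91 ± 0.25 in WT1A relative to WT1B, and STE3, the receptor for a-factor, was at −5.81 ± 0.14. All 7 a-specific genes were higher and all 5 alpha-specific genes were lower in WT1A. The other a-specific genes had differences of 4.98 (BAR1), 4.59 (STE6), 4.36 (AGA2), 3.95 (MFA1) and 2.15 (ASG7), and SAG1 and AFB1 had −2.72 and −4.49. Outside these lists, HMRA1 at 6.77 ± 0.09 was the highest and HMLALPHA1, a gene with shared probes, the lowest at −7.15 ± 0.14. They were followed by YNL146C-A, YER053C-A, GEM1 and YLR157W-E, at 3.51, 2.83, 2.77 and 2.65. The next lowest were YDR524W-C at −4.49, YOL155W-A at −3.18, YOR072W-B at −2.77 and YOL038C-A at −2.68. As deposited, 5429 of 5449 genes differed, 5419 of them lower in WT1A with a median of −2.20, and after centring the count was 3463, with 1883 higher and 1580 lower. The set of arrays and the mating type cannot be told apart here, so these counts do not describe the mating type alone.

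The comparison of rpb1-1 with WT1B asks how a mutant form of the largest polymerase subunit, known as a temperature-sensitive allele, alters steady-state RNA levels relative to other genes. Genes of the general stress response, respiration and the proteasome were higher in rpb1-1, and genes that mark alpha cells, including the pheromone gene MF(ALPHA)2, were lower. These list calls were lost with an estimated correlation, at adjusted p = 0.522 for stress, respiration and alpha-specific genes and 0.432 for the proteasome. HSP12, a small heat shock protein of stationary-phase cells, rose by 3.56 ± 0.22, and DDR2, another stress gene, by 3.46 ± 0.20. URA3, an enzyme of uracil synthesis and a common marker gene, fell by 6.21 ± 0.16 to a mean of 5.36, while the labels give the allele ura3-1 for all strains. The probe sets of another species had a median of 3.13 in that group. RPO21 itself was higher by 0.40 ± 0.07 and RPB2 by 0.63 ± 0.06.

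In all, 3348 genes changed in rpb1-1, 1725 higher and 1623 lower, and 623 of them by at least 1 on the log2 scale. The larger side turned after centring, with 1615 higher and 1775 lower, with array weights, with 1831 and 1863, and among the 623 genes, with 292 and 331. For 63.2% of genes the 3 mutant arrays did not overlap the 3 wild-type arrays, where chance gives 10%. The highest genes after GIS3 (YLR094C), at 4.25 ± 0.18, were HSP12, DDR2, ADR1, SUE1, HPF1, ATG8, HSP42, GAD1 and GUT2, from 3.56 down to 2.75. ADR1 (3.40 ± 0.18) activates genes for growth on ethanol, ATG8 (3.01 ± 0.16) acts in autophagy and GUT2 (2.75 ± 0.14) in glycerol use. The lowest genes after URA3 (YEL021W) were MF(ALPHA)2 at −5.40 ± 0.24, PHO11 at −4.22 ± 0.19 with shared probes, YOL014W at −4.21 ± 0.28 and PHM6 at −3.97 ± 0.30. IRC4, DCG1, STE3 and MIP6 followed at −3.81, −3.78, −3.73 and −3.68. IMD2, which encodes IMP dehydrogenase of guanine nucleotide synthesis and has shared probes, was at −3.61 ± 0.36.

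Of the 32 measured genes of the proteasome list, which includes the activator gene RPN4, 32 rose in rpb1-1 (32 adjusted over the list alone), among them PUP1 at 1.24 ± 0.06, RPT4 at 1.07 ± 0.06 and PRE10 at 0.98 ± 0.05 (camera adjusted p = 2.4e-16, and adjusted p = 0.432 with an estimated correlation). Respiration genes rose in 42 of 45 cases and none fell (42 adjusted over the list alone), with QCR10 at 1.78 ± 0.10, SDH3 at 1.44 ± 0.08 and ATP7 at 1.25 ± 0.07. Their camera adjusted p was 1.24e-15, and adjusted p = 0.522 with an estimated correlation. Of the 40 general stress genes 38 rose and 1 fell (40 adjusted over the list alone), with a median of 1.35 and MCR1 at 1.81 ± 0.11 (adjusted p = 1.66e-10, and adjusted p = 0.522 with an estimated correlation). The median was 0.95 once the main axis of differences between replicates was removed, which also takes away any mutant effect along that axis. Heat shock and chaperone genes rose in 25 of 30 cases with none lower (26 adjusted over the list alone), such as SSA3 at 1.92 ± 0.13 and CPR6 at 1.37 ± 0.10 (adjusted p = 2.69e-06, and adjusted p = 0.522 with an estimated correlation). Among 25 oxidative stress genes, 19 rose and 2 fell (22 adjusted over the list alone), and the regulator YAP1 rose by 1.41 ± 0.10 (adjusted p = 1.12e-05, and adjusted p = 0.432 with an estimated correlation).

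All 5 alpha-specific genes fell in rpb1-1 (5 adjusted over the list alone), with a median of −2.73, STE3 at −3.73 ± 0.13 and AFB1 at −1.94 ± 0.09 (adjusted p = 0.000173, and adjusted p = 0.522 with an estimated correlation). After centring, STE3 lay at −1.82 ± 0.24 in rpb1-1, 1.95 ± 0.11 in WT1B and −3.85 ± 0.03 in WT1A (SD, n = 3). SAG1, in the same order at −1.07 ± 0.06, 1.69 ± 0.14 and −1.03 ± 0.12, lay at the level of WT1A. MF(ALPHA)2 lay nearer to WT1A, as did STE3, at −2.65 ± 0.37, 2.79 ± 0.21 and −5.13 ± 0.14. MF(ALPHA)1 stayed nearer to WT1B, at 2.34 ± 0.26, 3.61 ± 0.10 and −5.98 ± 0.20, as did AFB1, at 1.43 ± 0.12, 3.41 ± 0.05 and −1.09 ± 0.09. Of 7 a-specific genes 3 rose and 3 fell, so alpha-specific transcripts fell without a common rise of a-specific ones. Pheromone response genes fell in 16 of 25 cases and rose in 2 (18 adjusted over the list alone), with FAR1, which arrests the cell cycle during mating, at −1.92 ± 0.16 (adjusted p = 0.00421, and adjusted p = 0.522 with an estimated correlation). Glycolysis genes fell in 10 of 19 cases and rose in 1 (11 adjusted over the list alone), with ENO1 at −0.83 ± 0.07 and HXK2 at −0.79 ± 0.07 (adjusted p = 0.00415, and adjusted p = 0.522 with an estimated correlation). Nucleotide synthesis genes fell in 17 of 32 cases and rose in 3 (20 adjusted over the list alone), with IMD4 at −1.09 ± 0.07 and ADE12 at −0.73 ± 0.06 beside URA3 (adjusted p = 0.00714, and adjusted p = 0.522 with an estimated correlation).

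Ribosomal protein genes fell in 36 of 128 cases and rose in 2 (27 adjusted over the list alone), with a median of −0.08 and RPS9A at −1.71 ± 0.20 (adjusted p = 0.00369, and adjusted p = 0.816 with an estimated correlation). The main axis of differences between replicates predicts −0.13 for this list, and its median was −0.024 once the axis was removed. Of 31 meiosis and sporulation genes 17 fell and 3 rose (20 adjusted over the list alone), among them SSP1 at −2.37 ± 0.22 and SPO11, which makes meiotic DNA breaks, at −2.21 ± 0.09 (adjusted p = 0.00884, and adjusted p = 0.522 with an estimated correlation). Ergosterol genes fell in 14 of 28 cases and rose in 2 (16 adjusted over the list alone), with ERG26 at −0.94 ± 0.08 and ERG9 at 0.64 ± 0.05 (adjusted p = 0.0317, and adjusted p = 0.522 with an estimated correlation). DNA replication genes rose in 29 of 55 cases and fell in 11 (41 adjusted over the list alone), as with TAH11 at 0.73 ± 0.07 and RRM3 at −0.70 ± 0.07. Repair genes rose in 29 of 65 cases and fell in 12 (41 adjusted over the list alone), with MUS81 at 1.41 ± 0.09 and, among the fallen, REV7 at −2.29 ± 0.11 and YKU80 at −1.75 ± 0.07. Checkpoint genes rose in 8 of 18 cases with none lower (8 adjusted over the list alone), with RAD17 at 0.81 ± 0.12 and RAD24 at 0.59 ± 0.07. These 3 lists passed no camera test (adjusted p of 0.0636, 0.121 and 0.150) and passed fry, at 0.00309, 0.00309 and 0.000178. Fry does not compare a list with the other genes, so no shift particular to these lists was shown. YRA1, an mRNA export factor, fell by 1.34 ± 0.08. A further quantile normalization ended the calls of the meiosis list (adjusted p = 0.225) and the ribosomal protein list (adjusted p = 0.0676). Leaving out the dimmest genes ended those of the meiosis list (adjusted p = 0.343) and the ergosterol list (adjusted p = 0.0507).

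**Figure D2:**
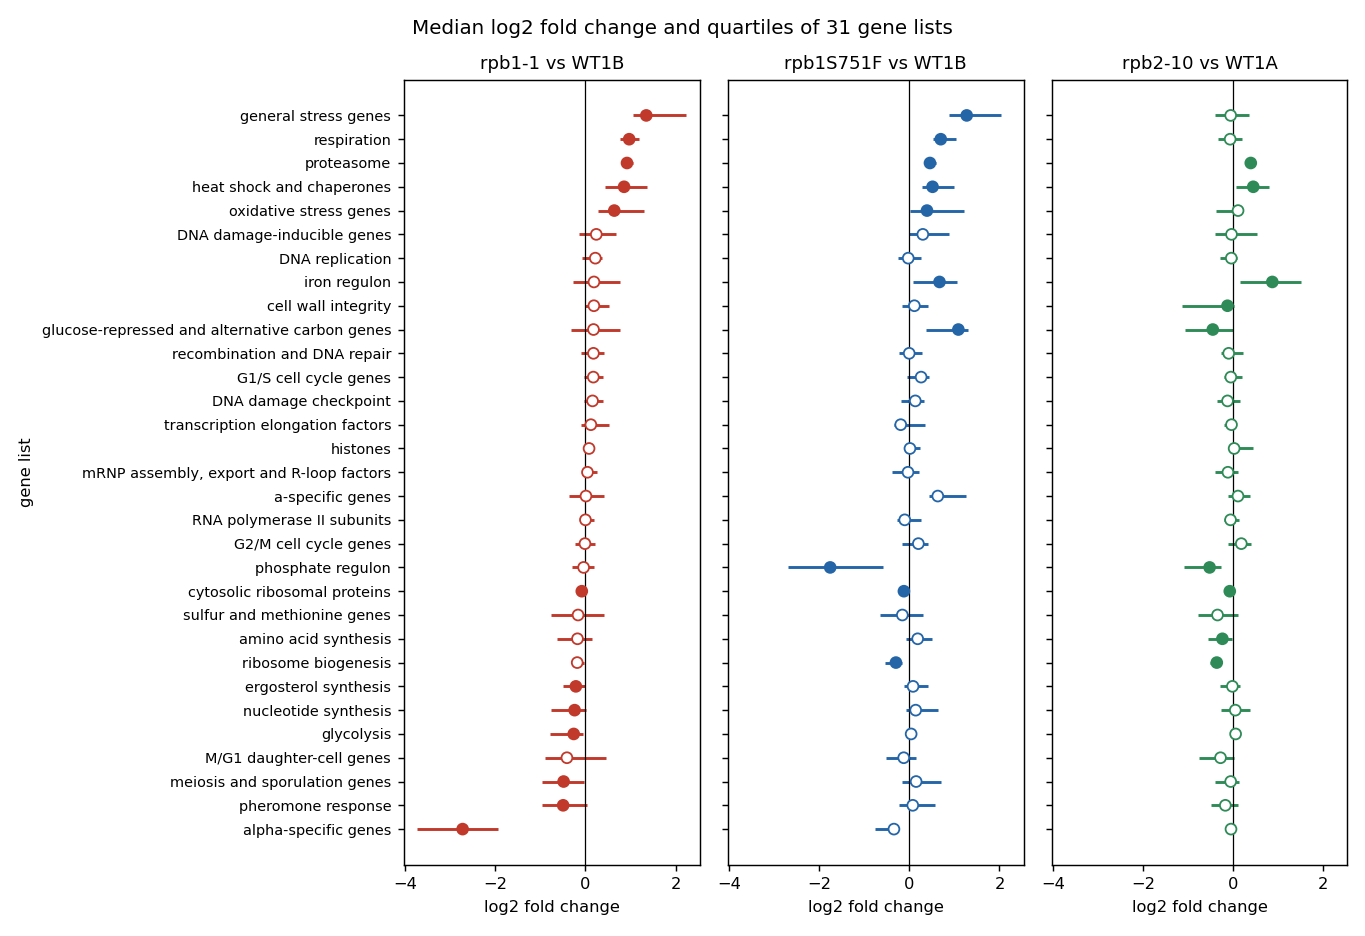
Median log2 fold change (dots) and quartiles (bars) of the 31 gene lists in each mutant against its own wild type, in the order of their medians in rpb1-1. Filled dots passed the camera test with the preset correlation; the general stress list has medians of 1.35, 1.27 and −0.06 in rpb1-1, rpb1S751F and rpb2-10.

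The comparison of rpb1S751F with WT1B asks the same question of an allele of the same gene. Genes of phosphate uptake and storage fell in rpb1S751F, while genes for growth on carbon sources other than glucose, stress genes and respiration genes rose. With an estimated correlation these list calls were lost, at adjusted p = 0.255, 0.792, 0.875 and 0.875 in this order, and the carbon list also lost its call without the dimmest genes (adjusted p = 0.388). SPL2, a regulator of low-affinity phosphate uptake, fell by 5.37 ± 0.18, and ADH2, the alcohol dehydrogenase that consumes ethanol, rose by 4.16 ± 0.13. HUG1 and RNR3, both induced by DNA damage and replication stress, rose. HUG1 rose by 2.30 ± 0.06 on the log2 scale and RNR3 2.82-fold on the linear scale, which is the smaller rise. RPO21 was higher by 0.37 ± 0.07 and RPB2 by 0.36 ± 0.06.

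In rpb1S751F 3503 genes changed, 1959 higher and 1544 lower, 613 of them by at least 1 (384 and 229), and 62.5% of genes had arrays that did not overlap the wild type. After ADH2 (YMR303C) the highest genes were FIT3, MBR1, ADR1, GUT2, GLK1, POT1, ECM8, ERR3 (shared probes) and RNP1, from 3.65 down to 2.88. FIT3 (3.65 ± 0.20) is a cell wall mannoprotein of iron uptake and POT1 (2.97 ± 0.17) the thiolase of fatty acid breakdown. After SPL2 (YHR136C) the lowest were PHM6 at −4.92 ± 0.30, MF(ALPHA)2 at −4.68 ± 0.24, PHO11 at −4.08 ± 0.19 and ATX1, a copper chaperone, at −3.56 ± 0.10. BDF2, MCH5, PRM7, YHB1 and YGR035C followed at −3.41, −3.35, −3.22, −3.21 and −3.10.

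Of 18 phosphate regulon genes 17 fell and none rose (17 adjusted over the list alone), with a median of −1.76, VTC3 at −1.93 ± 0.09 and PHO81, a regulator of the pathway, at −1.82 ± 0.07 (adjusted p = 8.96e-10, and adjusted p = 0.255 with an estimated correlation). Glucose-repressed and alternative carbon genes rose in 25 of 35 cases and fell in 3 (29 adjusted over the list alone), with MAL32 at 1.79 ± 0.10 (shared probes). Their camera adjusted p was 4.27e-05, and adjusted p = 0.792 with an estimated correlation. Respiration genes rose in 38 of 45 cases and fell in 1 (40 adjusted over the list alone), with IDH1 at 1.80 ± 0.15 and QCR2 at 1.32 ± 0.11 (adjusted p = 7.52e-09, and adjusted p = 0.875 with an estimated correlation). Of 40 general stress genes 35 rose and 1 fell (37 adjusted over the list alone), with ALD4 at 2.88 ± 0.20 and NQM1 at 2.28 ± 0.14 (adjusted p = 2.82e-07, and adjusted p = 0.875 with an estimated correlation). Their median went from 1.27 to 0.79 once the main axis of differences between replicates was removed, along with any mutant effect along that axis. Proteasome genes rose in 27 of 32 cases with none lower (27 adjusted over the list alone), with PUP1 at 0.80 ± 0.06 (adjusted p = 4.94e-07, and adjusted p = 0.875 with an estimated correlation).

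Heat shock and chaperone genes rose in 21 of 30 cases and fell in 1 (24 adjusted over the list alone), with SSA3 at 2.87 ± 0.13 (adjusted p = 0.00287, and adjusted p = 0.875 with an estimated correlation). Of 27 iron regulon genes 18 rose and 3 fell (22 adjusted over the list alone), with HMX1, a heme oxygenase, at 2.02 ± 0.09 (adjusted p = 0.0389, and adjusted p = 0.875 with an estimated correlation). Of 25 oxidative stress genes 17 rose and 4 fell (21 adjusted over the list alone), with GTT2 at 2.31 ± 0.12 and GPX2 at −2.64 ± 0.11 (adjusted p = 0.0389, and adjusted p = 0.875 with an estimated correlation). Ribosomal protein genes fell in 56 of 128 cases and rose in 1 (48 adjusted over the list alone), with RPS22B at −2.99 ± 0.15 and RPS28B at −0.65 ± 0.05 (adjusted p = 4.29e-06, and adjusted p = 0.875 with an estimated correlation). Ribosome biogenesis genes fell in 24 of 64 cases with none higher (20 adjusted over the list alone), with UTP9 at −0.69 ± 0.16 (adjusted p = 0.000348, and adjusted p = 0.905 with an estimated correlation). The ribosome biogenesis list did not pass fry (adjusted p = 0.126). Once the main axis of differences between replicates was removed, its median turned from −0.30 to 0.15, that of ribosomal proteins went from −0.12 to −0.057 (the axis predicts −0.13) and that of heat shock genes from 0.51 to 0.18 (the axis predicts 0.78).

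The alpha-specific list passed no camera test in rpb1S751F (fry adjusted p = 0.00053), with 3 of 5 genes lower, nor did the a-specific list (fry adjusted p = 0.00375), of which 6 of 7 genes rose, among them AGA2 at 2.14 ± 0.18 and MFA1 at 1.67 ± 0.14, while BAR1 fell by 2.86 ± 0.12. DNA damage-inducible genes rose in 11 of 20 cases and fell in 4 (15 adjusted over the list alone), and the list passed fry (adjusted p = 2.8e-05) and not camera (adjusted p = 0.116). In other lists without a camera call, ORC1, a subunit of the origin recognition complex, fell by 1.21 ± 0.09, YKU70 by 1.40 ± 0.12 and SUS1, an export and chromatin factor, by 1.45 ± 0.14, while MUS81 rose by 1.41 ± 0.09. Meiosis genes DMC1 and SGA1 rose by 1.59 ± 0.09 and 2.33 ± 0.12. Without the dimmest genes the calls of the iron list and the oxidative stress list also ended (adjusted p = 0.0654 for each). Without WT1B replicate 1 the iron and oxidative stress lists had adjusted p of 0.108 and 0.0792, without rpb1S751F replicate 2 of 0.0693 and 0.0568, and without shared probes the oxidative stress list had 0.0785.

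The comparison of rpb2-10 with WT1A concerns an allele of the second largest subunit, known from earlier work for slow elongation. In rpb2-10 18 of 27 iron regulon genes and 30 of 32 genes of the proteasome list rose, and 12 of 18 phosphate genes fell. These list calls were lost with an estimated correlation, at adjusted p = 0.995. FIT2, a cell wall mannoprotein of iron uptake, rose by 4.07 ± 0.46 and ARN1, a siderophore transporter, by 3.64 ± 0.21. CWP1, a cell wall mannoprotein, fell by 5.41 ± 0.15. HIS3, an enzyme of histidine synthesis and a common marker gene, fell by 6.20 ± 0.18 to a mean of 2.12, while the labels give the same his3 marker allele for all strains. The probe sets of another species had a median of 1.18 in that group. RPB2 differed by 0.00 ± 0.06 (adjusted p = 0.962) and RPO21 by 0.15 ± 0.07, which passed the test only after centring or quantile normalization, at 0.21 and 0.19.

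In rpb2-10 3105 genes changed, 1429 higher and 1676 lower, 352 of them by at least 1 (115 and 237), and 76.1% of genes had arrays that did not overlap the wild type. The larger side turned after centring, with 1660 higher and 1418 lower, and after quantile normalization, with 1633 and 1431. HBN1 at 3.96 ± 0.13, GIS3 at 3.63 ± 0.18 and YOR389W at 3.52 ± 0.09 were among the 10 highest, with YPL277C and YPL278C (both with shared probes) at 3.58 ± 0.10 and 3.56 ± 0.07. FIT3, TIS11, which acts in the response to low iron, and CBT1 were at 2.94 ± 0.20, 2.89 ± 0.34 and 2.48 ± 0.08. After HIS3 (YOR202W) and CWP1 (YKL096W) the lowest genes were YDL241W at −4.62 ± 0.18, PHO89, a sodium and phosphate transporter, at −4.60 ± 0.27 and PHO5, the secreted acid phosphatase, at −3.92 ± 0.17. YOL014W, OPT2, STP4, CYC7 and PIR3 followed at −3.91, −3.50, −3.27, −3.23 and −3.19.

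Genes of the proteasome list rose in 30 of 32 cases and fell in 1 in rpb2-10 (31 adjusted over the list alone), with RPN8 at 0.64 ± 0.07 and, as the fallen member, the activator gene RPN4, named after its value was seen, at −0.88 ± 0.16 (adjusted p = 3.8e-09, and adjusted p = 0.995 with an estimated correlation). Of 27 iron regulon genes 18 rose and 4 fell (22 adjusted over the list alone), and ISU1, a scaffold of iron-sulphur cluster assembly, was among the fallen at −1.10 ± 0.09 (adjusted p = 0.00036, and adjusted p = 0.995 with an estimated correlation). Of 18 phosphate genes 12 fell and 1 rose (13 adjusted over the list alone), with PHO81 at −0.78 ± 0.07 (adjusted p = 0.00106, and adjusted p = 0.995 with an estimated correlation). Heat shock and chaperone genes rose in 18 of 30 cases with none lower (18 adjusted over the list alone), with SSE2 at 1.67 ± 0.19 and CPR6 at 0.87 ± 0.10 (adjusted p = 0.00106, and adjusted p = 0.995 with an estimated correlation). Ribosome biogenesis genes fell in 32 of 64 cases with none higher (32 adjusted over the list alone), with NOP15 at −0.88 ± 0.18 (adjusted p = 0.00149, and adjusted p = 0.995 with an estimated correlation), and the list did not pass fry (adjusted p = 0.0871).

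Amino acid synthesis genes fell in 31 of 59 cases and rose in 7 in rpb2-10 (39 adjusted over the list alone), with ARG4 at −1.27 ± 0.10, ARO3 at −1.06 ± 0.09 and SER1 at 0.79 ± 0.06 (adjusted p = 0.00375, and adjusted p = 0.995 with an estimated correlation). Cell wall integrity genes fell in 12 of 26 cases and rose in 4 (16 adjusted over the list alone), with the kinase gene SLT2 at −1.73 ± 0.07 and PIR1 at −1.52 ± 0.06 (adjusted p = 0.0136, and adjusted p = 0.995 with an estimated correlation). Glucose-repressed genes fell in 17 of 35 cases and rose in 2 (18 adjusted over the list alone), with CTA1 at −2.04 ± 0.23 and HXT2 at −1.45 ± 0.12 (adjusted p = 0.0194, and adjusted p = 0.995 with an estimated correlation). Ribosomal protein genes fell in 18 of 128 cases and rose in 1 (11 adjusted over the list alone), with RPS14B at −0.71 ± 0.07 (adjusted p = 0.0345, adjusted p = 0.995 with an estimated correlation, and 0.0513 by fry). Neither general stress genes (8 of 40 higher, 9 lower) nor respiration genes (11 of 45 higher, 12 lower) passed camera or fry in rpb2-10 (fry adjusted p of 0.846 and 0.405).

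DNA replication genes fell in 18 of 55 cases and rose in 5 in rpb2-10 (23 adjusted over the list alone), with MCM5, of the replicative helicase, at −0.93 ± 0.09. Repair genes fell in 21 of 65 cases and rose in 15 (36 adjusted over the list alone), with RAD16 at −1.80 ± 0.14, RAD7 at −1.45 ± 0.08 and MMS2 at 0.86 ± 0.07. These lists passed no camera test (adjusted p of 0.436 and 0.757) and passed fry, at 0.0205 and 0.0474. HUG1, of the DNA damage-inducible list, rose by 1.64 ± 0.06. The calls of the glucose-repressed list ended without the dimmest genes (adjusted p = 0.491) or after quantile normalization (adjusted p = 0.106), and that of the ribosomal protein list after centring (adjusted p = 0.511). The ribosomal protein list also lost its call without WT1A replicate 1 (adjusted p = 0.106), rpb2-10 replicate 1 (0.0661) or rpb2-10 replicate 3 (0.0602), and in fits of fewer arrays it and the cell wall list had 0.0502.

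**Figure D3:**
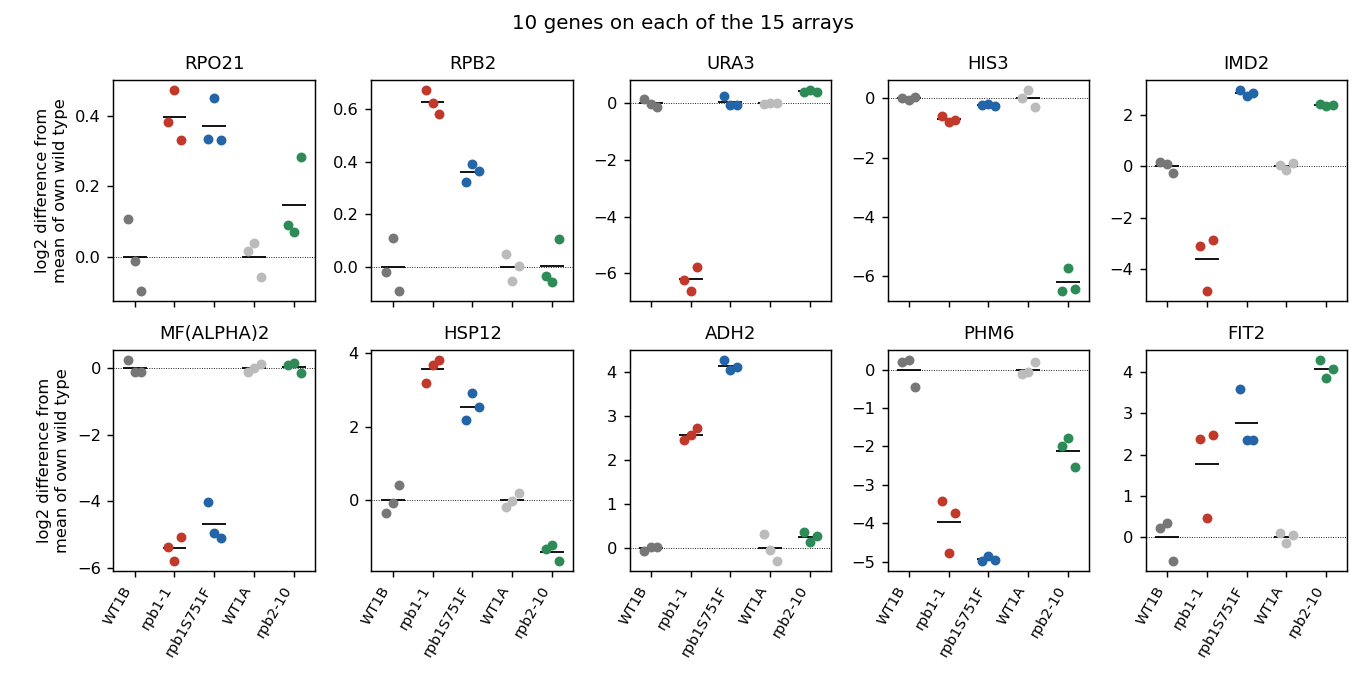
Log2 difference of each array from the mean of its own wild type for 10 genes, with 1 point per array and a line at each group mean. URA3 was low on the 3 rpb1-1 arrays and HIS3 on the 3 rpb2-10 arrays, and IMD2 lay below the wild type in rpb1-1 (−3.61) and above it in rpb1S751F (2.86) and rpb2-10 (2.39).

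The rpb1 alleles differed from each other in 3083 genes, 1488 higher and 1595 lower in rpb1-1, and 558 of them by at least 1, 130 higher and 428 lower. The larger side turned without the dimmest genes, with 1203 higher and 1040 lower, and after quantile normalization, with 1645 and 1482. Phosphate genes were higher in rpb1-1 than in rpb1S751F in 16 of 18 cases with none lower (16 adjusted over the list alone), as with SPL2 at 5.23 ± 0.18 and PHO89 at 3.65 ± 0.27 (adjusted p = 2.77e-07, and adjusted p = 0.302 with an estimated correlation). Proteasome genes were higher in 31 of 32 cases with none lower (31 adjusted over the list alone; adjusted p = 1.27e-10, and adjusted p = 0.486 with an estimated correlation). All 5 alpha-specific genes were lower (5 adjusted over the list alone; adjusted p = 0.00326, and adjusted p = 0.486 with an estimated correlation). Meiosis genes were lower in 19 of 31 cases with none higher (19 adjusted over the list alone; adjusted p = 2.81e-05, and adjusted p = 0.302 with an estimated correlation). Amino acid synthesis genes were lower in 36 of 59 cases and higher in 4 (41 adjusted over the list alone; adjusted p = 2.04e-05, and adjusted p = 0.486 with an estimated correlation). IMD2 was lower by 6.47, at −6.47 ± 0.36.

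The effects of the rpb1 alleles and rpb2-10 on stress and respiration differed by test. Respiration genes had a higher effect in rpb1-1 than in rpb2-10 in 38 of 45 cases with none lower (38 adjusted over the list alone; adjusted p = 9e-12, and adjusted p = 0.712 with an estimated correlation). The effect of rpb1S751F on respiration was higher than that of rpb2-10 in 39 of 45 genes and lower in 1 (40 adjusted over the list alone; adjusted p = 3.76e-08, and adjusted p = 0.995 with an estimated correlation). General stress genes had a higher effect in rpb1-1 in 30 of 40 cases and a lower one in 2 (36 adjusted over the list alone; adjusted p = 8.18e-07, and adjusted p = 0.712 with an estimated correlation). In rpb1S751F these numbers were 33 and 2 of 40 (36 adjusted over the list alone; adjusted p = 5.92e-06, and adjusted p = 0.995 with an estimated correlation). CYC7, an isoform of cytochrome c, differed most among the higher effects of rpb1-1, by 5.89 ± 0.39, with 2.66 ± 0.27 in rpb1-1 and −3.23 ± 0.27 in rpb2-10. Between rpb1-1 and rpb2-10 the effects on 3092 genes differed, and between rpb1S751F and rpb2-10 those on 2815 genes. In all these contrasts the subunit coincides with the mating type and the set of arrays, so the differences cannot be assigned to the subunit alone.

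Across the 3 mutants, 812 genes changed the same way, 467 higher and 345 lower, where independent lists would share 304.1, and 32 did so by at least 1. Part of the excess may come from the WT1B arrays, which the comparisons of both rpb1 alleles share. PHM6, PHO5 and PHO11 of the phosphate pathway fell in each mutant, with PHO5 at −1.97 ± 0.17 in rpb1-1, −2.89 ± 0.17 in rpb1S751F and −3.92 ± 0.17 in rpb2-10. The phosphate list as a whole did not shift in rpb1-1, with 4 of 18 genes higher, 5 lower and a median of −0.04 (camera adjusted p = 0.398). MEP2, an ammonium transporter, was at −3.56 ± 0.11, −2.41 ± 0.11 and −2.46 ± 0.11 in the same order. YOL014W, YMR230W-A and PRM7 also fell in each. FIT2, FIT3 and ADR1 rose in each, with FIT3 at 1.46 ± 0.20, 3.65 ± 0.20 and 2.94 ± 0.20 and ADR1 at 3.40 ± 0.18, 3.11 ± 0.18 and 1.55 ± 0.18.

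Across genes, log2 fold changes of rpb1-1 and rpb1S751F correlated with r = 0.508 and a covariance of 0.243. These comparisons share the WT1B arrays, and unchanged groups simulated against shared controls gave a mean r of 0.498 with a covariance of 0.00741, so the covariances differed by 0.236. In both mutants 1164 genes were higher and 851 lower, against 620.2 and 459.9 for independent lists, and 399 genes moved in opposite directions. With 3 control arrays the controls were not divided, and part of the excess over independent lists may come from the shared controls. The correlation was 0.116 between rpb1-1 and rpb2-10 and 0.223 between rpb1S751F and rpb2-10, which share no control, and genes are not independent replicates.

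**Figure D4:**
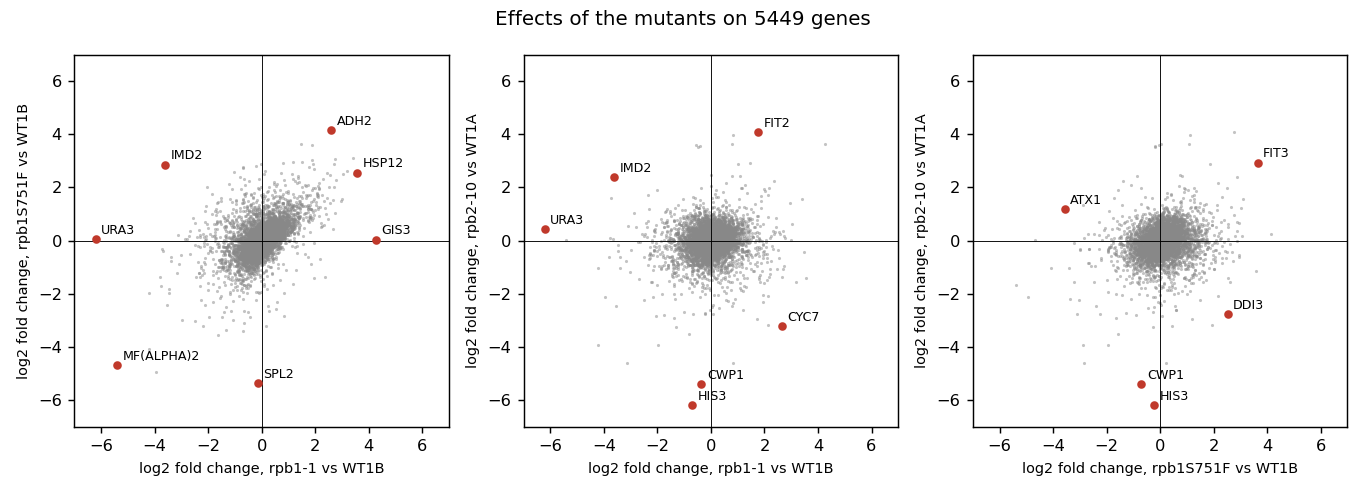
Log2 fold changes of the tested genes in pairs of mutants, each against its own wild type, with 1 dot per gene and red dots for genes named in the text. The correlation across genes is 0.508 for the rpb1 alleles, 0.116 for rpb1-1 and rpb2-10 and 0.223 for rpb1S751F and rpb2-10.

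Coding length was compared with the log2 fold change because the mutations affect the subunits of the polymerase that transcribes these genes. Spearman's rho across genes was 0.07 ± 0.02 in rpb1-1, 0.03 ± 0.01 in rpb1S751F and −0.11 ± 0.06 in rpb2-10 (SD over 3 mutant arrays against the wild-type mean). In rpb1S751F it was 0.00812 without WT1B replicate 1 and 0.0496 without WT1B replicate 2, and in rpb1-1 0.0414 without the dimmest genes and 0.0403 after quantile normalization. In rpb2-10, 197 of the 1089 longest genes, of 2109 bases or more, were higher and 389 lower, against 364 higher and 269 lower of the 1097 shortest, of at most 660 bases. In rpb1-1 the longest genes were higher in 375 cases and lower in 258, and the shortest higher in 297 and lower in 366.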

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

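The counts of other splits of the arrays were chosen beforehand, and the exchange of whole labels and the tests on HIS3, URA3, the stress genes and the unnamed probe sets were chosen after the results were seen.

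The rpb1 alleles, compared directly, differed in 3083 genes. IMD2 at −6.47, URA3 at −6.26, YFR012W-A at −4.07, YAL064W at −3.65 and YDR541C at −3.61 were the lowest in rpb1-1 relative to rpb1S751F. SPL2 at 5.23, GIS3 at 4.22, AQY2 at 3.75, PHO89 at 3.65 and YHB1 at 3.39 were the highest. The 6 arrays make 10 splits, too few for a share under 0.05, and the highest other split gave 381 genes against 3083. Every other split mixes the alleles and puts their difference into the residual. A lower count was therefore bound to follow and decides nothing about chance.

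The effects of rpb1-1 and rpb2-10, each against its own wild type, differed in 3092 genes by the test of the difference. URA3 (−6.64), IMD2 (−6.00), MF(ALPHA)2 (−5.43), STE3 (−5.34) and YPL277C (−4.14, shared probes) had the lowest differences. CYC7 (5.89), HIS3 (5.51), PHO89 (5.42), PIR3 (5.31) and CWP1 (5.05) had the highest. For rpb1S751F and rpb2-10 the effects on 2815 genes differed. ATX1 (−4.74), MF(ALPHA)2 (−4.71), QDR2 (−4.19), YPL278C (−3.74, shared probes) and YOR389W (−3.72) were lowest, and HIS3 (5.98), DDI3 (5.29, shared probes), PIR3 (5.13), YDL241W (4.85) and MBR1 (4.73) highest. The alpha-specific genes MF(ALPHA)2 and STE3 lay at −5.13 and −3.85 in WT1A after centring, against 2.79 and 1.95 in WT1B. They had little room to fall in rpb2-10, so their differences follow at least in part from the mating type. The subunit coincides with the mating type and the set of arrays, so these differences cannot be assigned to the subunit alone. Of 100 splits within each mutant and its wild type, 1 gave as many genes in each case, the real one, and the highest others gave 1708 and 1801. Splits that mix a mutant with its wild type carry strain differences in the residual, so these splits decide nothing about chance. A split outside those 100, with the labels of rpb2-10 and WT1A exchanged as wholes, tests the sum of the effects and gave 3472 and 3703 genes, more than the real ones.

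HIS3 in rpb2-10 and URA3 in rpb1-1 were low but above most probe sets of another species, at their 97.8th and 99.5th percentiles. The mean of HIS3 was 2.12, where those probe sets had a median of 1.18 and 95th percentiles of 1.84 to 1.87. For URA3 the mean was 5.36, with a median of 3.13 and 95th percentiles of 4.09 to 4.14. The labels give the same ura3-1 and his3 marker alleles for all 5 strains and so name no difference at these loci. On arrays exchanged between groups nothing was decided: 0 arrays of either mutant correlated best with another group, but whole groups exchanged would give the same. The genes beside HIS3 also fell in rpb2-10, MRM1 by 1.79 ± 0.07 and DED1 by 1.41 ± 0.18, as in 7 of 5417 genes, so an altered HIS3 locus in that strain is a candidate explanation (less lowered neighbour −1.41), although DED1 also fell by 0.89 in rpb1-1 and by 0.80 in rpb1S751F and an effect of rpb2-10 itself stays open. Beside URA3, GEA2 was higher by 0.27 ± 0.06 and TIM9 fell by 0.84 ± 0.10, so an altered URA3 locus and an effect of the mutation, which coincides with the strain, cannot be told apart.

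General stress genes were higher in rpb1-1 and rpb1S751F, and the main axis of differences between replicate cultures, with 54.4% of the residual variance in the alpha strains, also moved them. Scaled to the stress genes, that axis predicts medians of −1.20 and −1.13 for ribosome biogenesis genes, which had −0.18 and −0.30, so it is argued against as the whole cause. It may be part of it, which removing the axis cannot decide. The removal also takes away any mutant effect along the axis, so lower stress medians were bound to follow. It took the stress medians from 1.35 to 0.95 and from 1.27 to 0.79, and heat shock from 0.86 to 0.61 and from 0.51 to 0.18. Ribosomal proteins went from −0.08 to −0.024 and from −0.12 to −0.057, and ribosome biogenesis turned to 0.27 and 0.15. Heat shock genes also lay near the predicted 0.82 in rpb1-1 and below the predicted 0.78 in rpb1S751F. A further quantile normalization gave stress medians of 1.32 and 1.21. RMA values are already quantile-normalized, so little change was bound to follow and this decides nothing about scaling of the arrays. Scaling, a growth difference of another kind and an effect of the mutations stay open.

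Of 3470 unnamed probe sets that mark no control, 267 (7.69%) lay above the 95th percentile of the other species on every array. Of these, 70 were higher and 63 lower in rpb1-1, 89 and 51 in rpb1S751F, and 66 and 52 in rpb2-10. No explanation was tested.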

How the results depend on the processing

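The alternatives named in the methods were chosen before the data were examined, and 3 settings were added after: a fit of arrays normalized together, genes above background and no shared probes. They gave 2932, 3343 and 3289 genes for rpb1-1, 2974, 3493 and 3430 for rpb1S751F, and 3877, 3109 and 3061 for rpb2-10. Of the 3 mutants, rpb2-10 thus had the most genes in the fit of arrays normalized together and the fewest in the main fit. The planned use of both wild types as 1 control was not run, since their values are on different scales. No setting moved the median of a mutant comparison by over 0.1.

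With a log2 fold change of at least 1 the counts were 623 (rpb1-1), 613 (rpb1S751F), 352 (rpb2-10), 558 (allele contrast), 880 and 813 (effects of rpb1-1 and rpb1S751F against rpb2-10), and 32 genes changed the same way in all 3 mutants, against 531 at an adjusted p of 0.01. WT1A and WT1B differed in 3463 genes after centring and 3422 after quantile normalization, with 54.4% and 48.9% higher in WT1A against 0.184% as deposited.

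With camera and an estimated correlation, 0 lists were shifted in rpb1-1, 0 in rpb1S751F and 0 in rpb2-10, with 2, 1 and 0 at an unadjusted p under 0.05, and fry gave 22, 22 and 12. The correlation of effects of rpb1S751F and rpb2-10 was 0.296 without the dimmest genes. The length trend in rpb1-1 was 0.0414 without them and 0.0403 after quantile normalization. RPB2 in rpb2-10, at 0.00, was at −0.026 after quantile normalization and −0.0021 with array weights. RPO21 in rpb2-10 passed the test at 0.21 after centring and 0.19 after quantile normalization.

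Leaving out each array gave 3073–3299, 3159–3526 and 2637–2849 genes in rpb1-1, rpb1S751F and rpb2-10. The length trend was 0.0528–0.0954 in rpb1-1 and 0.00812 (without WT1B replicate 1) to 0.0496 (without WT1B replicate 2) in rpb1S751F, and RPB2 in rpb2-10 was at −0.047 to 0.035. Of 6122 values of 359 gene results over the settings other than the stricter thresholds, 6099 kept call and direction, 17 lost the call, 2 gained it and 4 turned direction. Most of these genes were chosen for large changes or small p in the same data, so most calls were likely to stay.

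Replicate numbers were not used as pairs, since correlations of arrays with the same number were mixed in sign or all negative. Deviations from the group means correlated by 0.32, −0.28 and −0.31 for rpb1-1 and WT1B, 0.48, −0.02 and 0.38 for rpb1S751F and WT1B, −0.12, −0.02 and −0.24 for rpb2-10 and WT1A, and 0.37, 0.50 and −0.29 for the rpb1 alleles. In this order 1, 2, 0 and 2 of 3 arrays matched their own number best. With the number as a replicate block the counts were 3393, 3532 and 3142, lists 12, 10 and 9, and the allele contrast 3129.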

Other observations

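The counts of other splits were chosen beforehand, and the tests on HUG1, IMD2 and the chromosome ends were chosen after the results were seen, as were the genes RNR2, IMD3, SIR2, HTL1 and RPN4.

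HUG1 and RNR3, genes induced by DNA damage, moved in opposite directions between the alleles of 1 subunit. Their list did not: 10 of 20 DNA damage-inducible genes rose and 4 fell in rpb1-1 (camera adjusted p = 0.190), and 11 rose and 4 fell in rpb1S751F. HUG1 fell by 0.68 ± 0.06 in rpb1-1 and rose by 2.30 ± 0.06 in rpb1S751F and 1.64 ± 0.06 in rpb2-10. In the same order RNR3 fell by 0.51 ± 0.12, rose 2.82-fold on the linear scale and rose by 0.62 ± 0.12. RNR2, another ribonucleotide reductase gene, fell in each, by 0.61 ± 0.08, 0.53 ± 0.08 and 0.41 ± 0.08. RPN4, an activator of proteasome genes, rose by 1.13 ± 0.16 in rpb1-1 and fell by 0.88 ± 0.16 in rpb2-10, while most other genes of the proteasome list, which includes RPN4, rose in both. HTL1, a subunit of a chromatin remodeller, fell by 1.17 ± 0.17 in rpb1-1 and by 2.65 ± 0.17 in rpb1S751F.

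IMD2 was at −3.61 ± 0.36 in rpb1-1, 2.86 ± 0.36 in rpb1S751F and 2.39 ± 0.36 in rpb2-10. Its probes are shared. IMD2 exceeded the more changed of IMD3 and IMD4 by 2.51, 2.14 and 1.80 (SE 0.384), so signal of IMD3 and IMD4 is argued against as the whole cause. Signal of any other sequence that shares the probes was not examined. IMD3 moved the same ways, at −1.10 ± 0.13, 0.72 ± 0.13 and 0.59 ± 0.13. IMD2, URA2 and URA8 are known to depend on nucleotide levels through the choice of start site, so a control shared by them was tested. In rpb1S751F 2 of 2 genes rose with IMD2, URA2 by 0.99 ± 0.09 and URA8 by 1.04 ± 0.07, so a shared control may act there. In rpb2-10 1 of 2 did, URA8 at 0.61 ± 0.07 with URA2 at −0.28 ± 0.09. In rpb1-1 0 of 2 passed the test by limma, with URA2 at 0.05 ± 0.09 and URA8 at 0.05 ± 0.07, so in these mutants a control shared with URA2 and URA8 stays open.

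For chromosome ends, genes with shared probes were left out, and the 10 outermost remaining genes of each of 32 ends were taken, 320 in all. Their median was −0.17 in rpb1-1 (82 higher, 130 lower), 0.21 in rpb1S751F (154 and 74) and −0.09 in rpb2-10 (78 and 124). In 10000 draws of other genes of like level the central 95% of medians were −0.09 to 0.04, 0.02 to 0.14 and −0.12 to −0.01, so dim signal is argued against in the rpb1 alleles. Neighbouring genes are not independent, and this form was chosen after windows of other sizes had been looked at. SIR2, needed for silencing at telomeres, fell by 0.50 ± 0.07 in rpb1-1, by 1.26 ± 0.07 in rpb1S751F and by 0.79 ± 0.07 in rpb2-10. Weaker silencing through lower SIR2 as a cause of the rise in rpb1S751F stays open, since the median of −0.17 in rpb1-1 comes from another strain with a smaller fall of SIR2.

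Splits of the 6 arrays of each comparison number 10 with the real one included, too few for a share under 0.05. In each of the comparisons rpb1-1, rpb1S751F, rpb2-10 and WT1A against WT1B, 1 split gave as many genes, the real one, with 3348, 3503, 3105 and 5429 genes, and the highest other split gave 0 by limma (690, 1268, 130 and 10 at an unadjusted p under 0.05). Mixed splits put the difference between the groups into the residual, so lower counts were bound to follow here too. For gene lists, with the real split counted, 5 of 10 splits gave as many as rpb1-1, 8 of 10 as many as rpb1S751F and 3 of 10 as many as rpb2-10. The real splits gave 12, 10 and 9 lists against highest others of 18, 18 and 10. Counts of shifted lists at the preset correlation therefore do not set the real grouping apart. The other splits keep part of the mutant effect, and no test here separates it from differences among replicates. For the genes changed the same way in all 3 mutants, 1 of 100 splits within each mating type gave as many, the real one, with 812 against a highest other of 0. Splits that mix strains put the differences between strains into the residual, so a count of 0 was bound to follow and this comparison decides nothing about chance.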
